A study of Mus musculus with 6 samples.

How the data were processed

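Single-cell gene expression was measured in 6 libraries, 1 per group: CD45-sorted cells of control, anti-PD-1, CCL21-DC and combination mice, and cells labelled CD3 of control and combination mice. The protocol in the labels describes subcutaneous tumours and a sort of viable CD45-positive cells for every library, while the labels give the tissue as lung and 2 libraries as CD3; how the latter were selected, and how many mice gave each library, is not stated. Per the labels, the authors used Cell Ranger 3.1.0 with the mouse build mm10, and Scanpy 1.6.0 in a role that is not stated. Each library came as 3 files. The deposited matrix files hold raw UMI counts per gene and cell barcode, not normalised, for 31053 genes; the other files hold the gene names and the barcodes in matrix order. Every deposited barcode had at least 500 UMIs, and the filter behind this is not stated.

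The libraries held 52582276, 43641587, 36578793, 42851544, 56074937 and 43663671 UMIs in the order above, 275392808 in 30129 barcodes. Many barcodes appeared in several libraries: 23691 in 1 library only, and 528, 265, 227, 317 and 349 in 2, 3, 4, 5 and all 6. Such a barcode was kept only in the library where it had at least 5 times the UMIs of any other, which left out 5117 entries, or 12.5%, 18.9%, 14.9%, 20.0%, 11.9% and 24.1% of the libraries. Barcodes with under 200 genes (373) and with over 10% mitochondrial UMIs (1165) were then left out. Scrublet, as in Scanpy 1.11.5, called 93 of the remaining 23474 cells (0.396%) as doublets. A caller that marks under 0.5% of over 5000 cells has not worked, so possible doublets were left out by their transcripts besides the called cells. A cell was left out when it passed the panels of 2 of 4 lineages, each with at least 3 UMIs of the panel and at least 5 (T, 8 genes), 50 (neutrophil, 8 genes), 20 (phagocyte, 14 genes) or 5 (tumour epithelium, 8 genes) of its UMIs per 10000. This took out 4068 cells (17.4%), or 13.1%, 18.9%, 15.2%, 16.9%, 16.5% and 26.3% of the libraries, and 19313 cells were kept. Of the cells taken out, 2363 passed the neutrophil and phagocyte panels alone, against 1632 kept cells that passed the phagocyte panel alone. Single cells that express genes of both panels would be taken out too, so not all of these need be doublets. Shares within phagocyte-like cells were not repeated without this filter.

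The comparisons, gene lists, marker lists, rule for named genes and most alternatives were fixed before the data were examined. The filters on shared barcodes and on cells of 2 lineages, the second clustering of phagocyte-like cells and the setting aside of mixed and unnamed subclusters were added once the barcodes and clusters had been seen, and the filters as first planned are among the alternatives.

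All 6 libraries were clustered together with Scanpy 1.11.5 and igraph 0.11.9. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with the library as batch, without T cell receptor, immunoglobulin segment, ribosomal, mitochondrial, hemoglobin and sex-linked genes, and 30 principal components, 15 exact nearest neighbours and Leiden resolution 1 were used. Clusters were named from 19 lists of cell type markers, with at least 3 markers higher than in other clusters and detected in at least 20% of cells and a mean log2 fold of at least 0.5, and were called X-like. Leading genes were Cd3g, Cd3d and Cd3e for T-like, S100a8, S100a9 and G0s2 for neutrophil-like, Lyz2, H2-Ab1 and Apoe for phagocyte-like, Krt18, Krt8 and Krt19 for tumour epithelium-like, Gzma and Ncr1 for NK-like, Cd79a and Ms4a1 for B-like, Siglech for pDC-like and Col1a1 for fibroblast-like clusters. Clusters with markers of 2 lineages among their 10 leading genes, or a median Scrublet score of at least 0.15, were set aside as mixed, and those that met no name as unnamed. T-like and phagocyte-like cells were clustered again in the same way, T-like cells without the proliferation genes and with 5 lists of subset markers; Cd8a and Gzmf led CD8-like, Cd40lg and Tnfsf8 conventional CD4-like, Foxp3 and Ikzf2 Treg-like, and S1pr1 and Tcf7 naive-like subclusters, while C1qa led macrophage-like, Ly6c2 monocyte-like, Xcr1 cDC1-like and Fscn1 mregDC-like ones. Median UMIs per cell in the order of the libraries were 4548.5, 4021, 4297, 3171, 2910 and 3538 in T-like cells, 2364.5, 2338, 2365.5, 3416.5, 1294 and 2380 in neutrophil-like cells, and 8817, 7387, 7936, 6344, 6840 and 8372 in phagocyte-like cells.

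Shares are given with exact Clopper-Pearson 95% intervals. For expression, UMIs were summed over the cells of a class in a library, in classes with at least 50 cells, and given per 1000000 UMIs (CPM) with exact Poisson intervals. Ratios have 0.5 UMI added to each count and 1 to each total, with exact conditional binomial intervals. A gene at 0 was given a limit of 3 counts in the class sum, and a class without cells a limit of 3 cells. Cells are not replicates and each group had 1 library, so no test was made. For each of 21 gene lists, the median log2 ratio was taken over members with at least 10 UMIs in both sums together, where at least 3 were measured, with an interval from 200 Poisson redraws, and compared with 10000 random lists of the same size drawn from 50 bins of expression. The lists were interferon-gamma response, type I interferon response, MHC class I, MHC class II, cytotoxicity, inhibitory receptors, naive or stem-like, Treg effector, T cell residency, T helper, proliferation, suppressive macrophage, inflammatory, chemokine, CCL21 axis, dendritic cell maturation, suppressive neutrophil, hypoxia and glycolysis, oxidative phosphorylation, lysosome and lipid, and dissociation stress.

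Genes were named by size alone: in T-like, neutrophil-like and phagocyte-like cells of the CD45 libraries and in the CD8-like, conventional CD4-like and Treg-like cells of the CD3 libraries, the 5 highest and the 5 lowest ratios, ranked by the interval bound nearest to 1. They needed at least 50 UMIs in both sums together and 20 CPM in the higher library. T cell receptor and immunoglobulin segments, ribosomal, mitochondrial and hemoglobin genes, unnamed gene models and genes under 10% of their highest CPM in another class of the library (free RNA) were left out. Members of the fixed lists were named besides. Positions come from GENCODE release M21 on GRCm38. The additive sum used genes with at least 200 UMIs, and the comparison between the CD45 and CD3 libraries genes with at least 50 UMIs in each pair. Correlations without any effect came from 100 redraws of the pooled profiles.

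The alternatives kept called doublets, allowed 20% mitochondrial UMIs, asked for 500 genes per cell, used Leiden resolutions of 0.5 and 2, took shares of cells other than neutrophil-like ones, gated T cells and their subsets on transcripts (the subsets after thinning to 1000 UMIs), scaled sums by TMM factors, averaged CPM over cells, asked for 50 UMIs per list member or 200 in each pair, kept only list members that passed the free RNA criterion, or added 5 UMIs to each count. The ratios and lists were tested on simulated data with known folds in 9239 genes: 98%, 86%, 94% and 100% of genes set to a fold of 0.25, 0.5, 2 and 4 came out on the right side, the intervals of unchanged genes covered the truth in 95.9%, and 19 of 20 lists without an effect fell inside the random range. These were Poisson draws without variation between cells or libraries. Their totals were far above those of small classes, such as the 260652 UMIs of conventional CD4-like cells in the CD3 control. The lists without an effect were random draws of unchanged genes. They do not show how often a list of genes that vary together falls outside the random range. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 were used, with random seed 0.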

Results

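Gene expression was measured in single cells from 6 libraries of mouse tumours, prepared with 10x Genomics 3' version 3 chemistry, which tags each captured transcript with a unique molecular identifier (UMI). FVB mice aged 7 to 9 weeks carried subcutaneous lung cancer tumours of about 50 mm^3. They were left as controls or were given 200 µg of an antibody against the inhibitory T cell receptor PD-1 into the abdomen, 1000000 dendritic cells making the chemokine CCL21 (CCL21-DC) into the tumour, or the combination. The labels put 1 library in each of 6 groups: CD45-sorted cells of control, anti-PD-1, CCL21-DC and combination mice, and cells labelled CD3 of control and combination mice. In that order the libraries held 52582276, 43641587, 36578793, 42851544, 56074937 and 43663671 UMIs in 6068, 4667, 3914, 6191, 4841 and 4448 barcodes. After filtering, 4408, 2943, 2630, 3918, 3059 and 2355 cells were kept, with medians of 3388, 3650, 4065, 3523, 6809 and 3638 UMIs per cell. With 1 library per group there was no test and no p-value, and a difference between treatments could not be separated from a difference between libraries. Intervals in brackets are 95% intervals and cover counting error only. Each median log2 ratio of a gene list named below lay outside the central 95% of 10000 random lists matched on size and expression, unless the text says otherwise.

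The first comparison, across the 4 CD45 libraries, asks how the makeup of the immune cells differed between treatments. T-like cells made up 12.9% of kept cells in the control library, 19.2% after anti-PD-1, 21.9% after CCL21-DC and 38.4% after the combination. The share was thus 1.48-fold [1.32 to 1.67], 1.69-fold [1.5 to 1.90] and 2.97-fold [2.69 to 3.27] that of the control. The combination library's T-like share was also 2.00-fold [1.81 to 2.21] that of anti-PD-1 and 1.75-fold [1.59 to 1.93] that of CCL21-DC. Neutrophil-like cells, the largest class, made up 62.8% in the control and 51.7%, 47.8% and 41.3% after the treatments.

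Among the smaller classes, NK-like cells made up 2.65% of the control library, 4.83% after anti-PD-1 and 4.6% after CCL21-DC, which is 1.82-fold [1.41 to 2.34] and 1.73-fold [1.33 to 2.25] the control. In the combination library their share was 2.5%, a ratio of 0.942 [0.713 to 1.24]. B-like cells made up 0.386%, 0.340%, 0.152% and 2.86% of the 4 libraries, so that the combination share was 7.41-fold [4.43 to 13.2] the control share. Mononuclear phagocyte-like cells, called phagocyte-like from here on, made up 7.42%, 8.49%, 9.24% and 6.25%. Within them, cells named monocyte-like formed 33.6% in the control and 60.4%, 51.4% and 59.6% after the treatments, while macrophage-like cells formed 47.4%, 26.4%, 38.3% and 27.3%. The pair labelled CD3 did not repeat this, with 21.2% monocyte-like cells in its control and 20.5% in its combination, and 70.8% and 70.9% macrophage-like cells. Monocyte-like subclusters 2 and 6 had mean log2 folds of 0.55 and 0.52, near the naming limit of 0.5. In the CD45 libraries subcluster 2 held 5 control cells and 34, 22 and 26 after the treatments. Dendritic cells of the cDC1-like kind formed 14.1%, 9.20%, 5.76% and 6.12% of phagocyte-like cells, and mature dendritic (mregDC-like) cells 4.89%, 4.00%, 4.53% and 6.94%. The pDC-like share was 1.16%, 1.22%, 1.03% and 0.408%, and the fibroblast-like share 0.703%, 0.612%, 0.494% and 0.153%. Tumour epithelium-like cells, which a CD45 sort should remove, made up 9.32%, 11.0%, 11.6% and 6.51%.

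Shares of one sample are tied to each other, and the T-like ratio of the combination was 1.88 among cells other than neutrophil-like ones. There the tumour-like ratios turned to 0.906 after anti-PD-1 and 0.887 after CCL21-DC, and the phagocyte-like ratio after CCL21-DC to 0.888. When cells had to hold at least 500 genes the T-like ratio of CCL21-DC turned to 0.964, because many T-like cells then fell into clusters called mixed. These were 1706 of 5015, 65.2% of those in the CCL21-DC library and 40.7% of those in the control. A gate without clusters gave T cell shares of 12.8%, 18.5%, 22.7% and 34.3%. It asked for at least 2 UMIs of Cd3e, Cd3d, Cd3g and Trac together and none of Lyz2, Cd79a and C1qb. The gate was run on the main set of kept cells, not at 500 genes. Cells kept out of the named classes as mixed made up 0.703%, 1.56%, 1.33% and 0.893%, and unnamed cells 1.93%, 1.09%, 1.86% and 0.715%. With cells holding the transcripts of 2 lineages and barcodes found in several libraries also kept, the tumour-like ratio of the combination turned from 0.698 to 1.30.

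**Figure D1:**
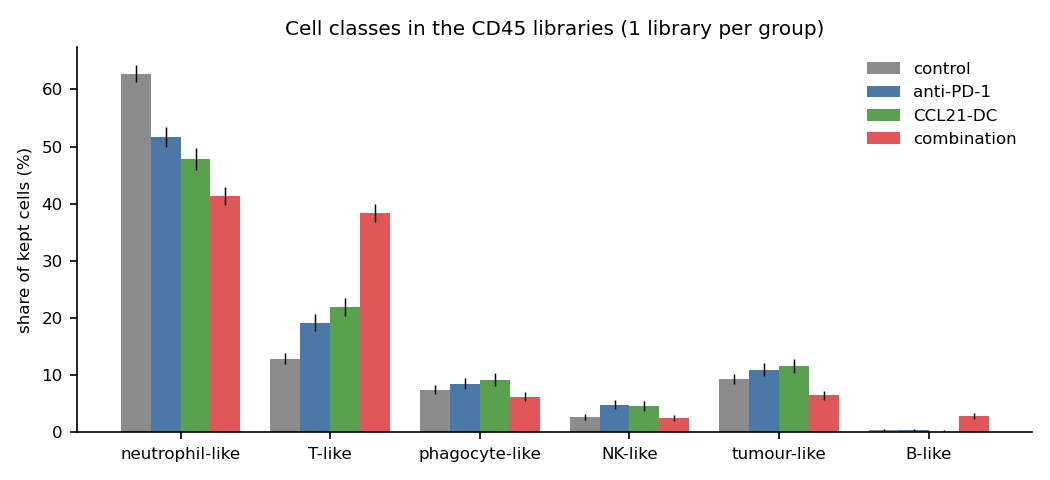
Bars give the percent of kept cells in each class for the 4 CD45 libraries, with error bars for exact 95% binomial intervals. T-like cells were 12.9% of the control and 38.4% of the combination library, and neutrophil-like cells 62.8% and 41.3%.

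The next comparison looks inside the T-like cells of the CD45 libraries, 570 in the control, 565 after anti-PD-1, 575 after CCL21-DC and 1503 after the combination, and asks which subsets differed. The combination library had the most naive-like T cells, 36.9% of T-like cells against 10.0% in the control, a ratio of 3.69 [2.81 to 4.94]. After CCL21-DC alone they formed 3.13% (0.313-fold [0.173 to 0.540]), and after anti-PD-1 alone 13.5%, with an interval of the ratio of 0.942 to 1.93. Regulatory T (Treg-like) cells, which restrain other T cells, formed 23.5% in the control, 21.9% after anti-PD-1, 13.9% after CCL21-DC and 6.99% after the combination, where the ratio was 0.297 [0.228 to 0.387]. Conventional CD4-like cells formed 22.6%, 27.4%, 44.3% and 25.1%, highest after CCL21-DC at 1.96-fold [1.58 to 2.44] the control. CD8-like cells formed 43.9%, 37.2%, 38.6% and 31.0%.

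With naive-like cells set aside, CD8-like cells formed 48.7% of the rest in the control and 49.2% in the combination, while Treg-like cells formed 26.1% and 11.1%, a ratio of 0.424 [0.325 to 0.552]. The naive-like cells were 1.29%, 2.58%, 0.684% and 14.2% of all kept cells. T-like cells other than naive-like ones were 11.6%, 16.6%, 21.2% and 24.2% of kept cells, which puts the combination at 2.08-fold [1.87 to 2.32] the control. Allowing up to 20% mitochondrial UMIs moved the naive-like ratio of the combination to 5.74. A gate on subset transcripts, after thinning each cell to 1000 UMIs, moved the Treg-like ratio to 0.448. The Treg-like ratio of CCL21-DC, 0.592 [0.443 to 0.786], became 1.01 when cells had to hold at least 500 genes. The T-like cells lay most often in subcluster 2 in the control (21.2%) and anti-PD-1 (20.0%), 7 in the CCL21-DC (38.4%) and 4 in the combination library (21.0%).

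**Figure D2:**
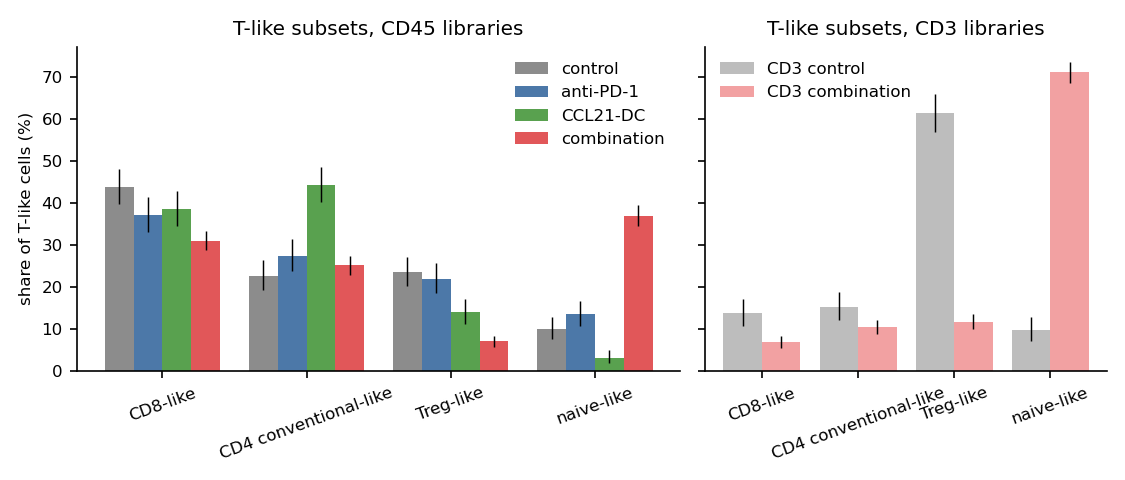
Bars give the percent of T-like cells in each T subset, in the 4 CD45 libraries and in the 2 CD3 libraries, with error bars for exact 95% binomial intervals. Naive-like cells formed 36.9% and Treg-like cells 6.99% in the CD45 combination library, against 10.0% and 23.5% in its control.

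Expression within the classes was then compared with the control, to ask which genes differed within each kind of cell. After anti-PD-1 alone, T-like cells had higher transcripts of the interferon-gamma response, with a list median log2 ratio of 0.52 and all 17 measured members higher, above each of the 10000 random lists. Irf1, a transcription factor of that response, was 1.81-fold [1.56 to 2.11] the control, Gbp2 1.67-fold, and the interferon-induced GTPase Irgm1 2.32-fold. The naive or stem-like list was higher (0.67, 10 members higher and 2 lower), as were the type I interferon list (0.32, 13 and 2), the T helper list (0.41, 5 and 3) and the Treg effector list (0.22, 12 and 5). The type I interferon median turned to -0.06 when each cell was given equal weight. Inhibitory receptors were lower (-0.24, 3 higher and 8 lower), with Tox, a regulator of T cell exhaustion, 2.05-fold lower and Pdcd1, the gene of PD-1, at 0.818-fold [0.75 to 0.891]. Proliferation genes were also lower (-0.23, 4 and 14), with Top2a at 0.734-fold. Within subsets the interferon-gamma list stood apart in Treg-like (0.39) and naive-like cells (0.71) but not in CD8-like (0.15) or conventional CD4-like ones (0.22). The type I interferon and T helper lists did so in Treg-like cells alone, inhibitory receptors in CD8-like cells alone, and proliferation genes in no subset (-0.01 in CD8-like cells). Within CD8-like cells the cytotoxicity list was higher (0.28, 12 and 4), as was the dissociation stress list (0.33, 12 and 3), which was also at 0.24 in all T-like cells. The granule protease Gzmb was 1.99-fold [1.90 to 2.08], the cytokines Ifng and Tnf were 1.89-fold and 2.48-fold, and Gzmc was 0.608-fold the control.

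The myeloid cells of the anti-PD-1 library also had more transcripts of the interferon-gamma response. In neutrophil-like cells its median was 0.98 with 17 of 17 members higher, and in phagocyte-like cells 1.11 with 16 higher and 2 lower. Irgm1 was 3.79-fold the control in the first and 4.90-fold in the second, and Cd274, the gene of the PD-1 ligand PD-L1, 1.97-fold and 2.59-fold. The inflammatory list was higher in both (0.71, 16 and 1; 0.95, 18 and 0). Nos2, the inducible nitric oxide synthase, was 3.94-fold in neutrophil-like and 10.8-fold [8.81 to 13.4] in phagocyte-like cells. In phagocyte-like cells the proliferation list stood at -1.88, with 1 member higher and 17 lower, among them Mki67 at 0.225-fold. Chemokine genes were lower there (-0.27, 3 and 10), and the chemokine Cxcl9 was at 0.908-fold where Cxcl10 was at 3.25-fold.

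By the rule on size, the genes named as highest after anti-PD-1 in T-like cells were Irgm2 (4.14-fold [2.55 to 7.28]), Ccr7 (2.39-fold [2.09 to 2.76]), Kdm6b, Ecm1 and Cnih2. The lowest were Slc16a11 (5.94-fold lower), the chemokine Ccl1 (3.52-fold lower), Nrgn, Spp1 and Gzmg. Over 50% of the UMIs of Gzmg in the control came from 1 cell, and both Gzmg and Spp1 changed sides when cells had to hold at least 500 genes. In neutrophil-like cells Csf3, the granulocyte growth factor, was 7.02-fold [5.33 to 9.47] and tissue factor, F3, 5.25-fold [4.89 to 5.64] the control, beside Serpinb2, Il1f6 and Gbp4. Ltc4s, an enzyme of leukotriene synthesis, was 6.65-fold lower and Siglecf 4.39-fold lower, beside Nol7, H1f0 and Camkk1. In phagocyte-like cells Rsad2 was 5.71-fold, Pdpn 5.15-fold and Inhba 4.15-fold the control, while Retnla was 16.9-fold lower, the complement gene C1qb 5.05-fold lower, and Akap5, Ccna2 and Cenpf were also among the lowest, Ccna2 with a log2 ratio of 0.15 under the first planned filters. Ifng was named there too, but over 50% of its UMIs came from 1 cell and it turned under 2 alternatives.

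After CCL21-DC alone, all T-like cells as 1 class had more transcripts of the T helper and dissociation stress lists. The T helper list had a median of 0.73, with 8 members higher and 2 lower, and 0.46 when cells had to hold at least 500 genes. Within subsets it stood apart in Treg-like cells alone (0.66), not in CD8-like (0.39) or conventional CD4-like ones (0.35), whose share of T-like cells was 1.96-fold the control. Ifng was 2.54-fold [2.36 to 2.74], the type 2 cytokine Il13 7.18-fold [4.91 to 11.2] and its regulator Gata3 1.95-fold the control. An unnamed subcluster of 102 cells led by Il13 and Il5 was left out of the T-like class in all libraries. The dissociation stress list was at 0.66 (13 and 2), with Fos at 2.70-fold, Egr1 at 2.75-fold and Hspa1b at 1.85-fold, and the receptor-induced genes Nr4a3 and Nr4a1 were 2.93-fold and 2.58-fold. The list of that name holds genes that handling of tissue also induces. The interferon-gamma list was higher (0.34, 12 and 4), as were T cell residency (0.49, 9 and 2), chemokine (0.48), cytotoxicity (0.28, 10 and 6) and naive or stem-like genes (0.31, 9 and 3); the last pair turned to -0.034 and -0.0042 with equal weight per cell. Proliferation (-0.46, 2 and 16), oxidative phosphorylation (-0.29, 0 and 15) and MHC class II genes (-0.47, 1 and 5) were lower, the last at 0.017 under the first planned filters and apart in no subset. Within CD8-like cells the proliferation list was not apart (-0.11). Pdcd1 was 0.748-fold and Tox 0.407-fold the control, although the inhibitory receptor list as a whole was near 0 (-0.01, not apart from random lists). In CD8-like cells the naive or stem-like list was 0.99 (10 and 2), with Klf2 at 2.74-fold, and cytotoxicity 0.25 (11 and 5), with Gzmb at 1.6-fold, Ifng at 1.65-fold and Prf1, the gene of perforin, at 1.32-fold.

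In neutrophil-like cells of the CCL21-DC library, type I interferon genes were higher with 16 of 16 members (0.96), and interferon-gamma (0.56, 16 and 1), inflammatory (0.79, 17 and 0) and MHC class I genes (0.46, 13 and 2) with most of theirs. Irgm1 was 2.84-fold, the chemokine Ccl4 2.41-fold and the prostaglandin synthase Ptgs2 2.29-fold the control. In phagocyte-like cells the interferon-gamma list was at 0.81 (15 and 3), with Iigp1 at 2.80-fold, Socs1, a brake on cytokine signals, at 3.33-fold and Cxcl9 at 0.671-fold. Hypoxia and glycolysis genes (0.68, 17 and 1) and lysosome and lipid genes (0.38, 12 and 4) were higher there, and proliferation genes lower (-1.80, 0 and 18).

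The genes named by size after CCL21-DC included Kdm6b (2.65-fold) among the highest of T-like cells, and Slc16a11 (3.99-fold lower), Nrgn, Ccl1, Spp1 and again Gzmg, mostly from 1 control cell, among the lowest. In neutrophil-like cells Gbp4 was 6.63-fold, Serpinb2 7.84-fold, Csf3 5.45-fold and F3 4.75-fold the control, Ltc4s was 4.76-fold lower, and H1f0, Hist1h1c, Tsc22d3 and Mrps14 were the other lowest. Mmp13 was 12.8-fold there, from 1 cell for the most part, and lower than the control under the first planned filters. In phagocyte-like cells Nos2 was 9.96-fold, Rsad2 8.64-fold and Inhba 5.12-fold, beside Serpinb2, mostly from 1 cell, and Atp6v0d2 at 18.3-fold [10.1 to 41.0], which was at a log2 ratio of -0.09 when cells with transcripts of 2 lineages were kept. Atp6v0d2 was also among the leading genes of an unnamed cluster outside all classes. That cluster held 65 control, 21 anti-PD-1, 8 CCL21-DC and 15 combination cells of the CD45 libraries. The lowest genes in phagocyte-like cells were genes of the cell cycle, Cenpf (14.0-fold lower), Tpx2 (9.28-fold lower), Birc5 and Ube2c, and the anchoring protein gene Akap5, which had no UMI after CCL21-DC and was at least 17.4-fold lower, taken at a limit of 3 counts in the class sum.

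After the combination, interferon genes were higher in T-like cells than in the control, by medians of 0.86 for interferon-gamma (14 and 4) and 0.85 for type I interferon (14 and 1). Irf1 was 2.14-fold, Socs1 2.35-fold, Irgm2 4.85-fold [3.11 to 8.31] and Ifngr2, part of the interferon-gamma receptor, 7.98-fold [4.88 to 14.9]. Treg effector genes were lower (-0.56, 2 and 15), with Foxp3 at 0.546-fold and Ctla4 at 0.611-fold, as were inhibitory receptors (-0.62, 1 and 10), with Pdcd1 at 0.651-fold [0.603 to 0.703], and proliferation genes (-0.78, 0 and 18). The 1 inhibitory receptor that was higher was Havcr2, at 1.28-fold. Within Treg-like cells Treg effector genes (0.23) and inhibitory receptors (0.45) were higher instead, and Treg effector genes were also higher within CD8-like cells (0.50). The naive or stem-like list was at 0.95 (12 and 1), with Tcf7 at 2.67-fold and Lef1 at 2.93-fold, and was not apart within conventional CD4-like (0.08) or naive-like cells (-0.12). The subset shares above differed as well: S1pr1, Dapl1, Ccr7, Klf2, Ifngr2, Trib2, Il6ra and Rflnb mark or lead naive-like clusters, Klrg1, Itgb8, Ikzf2, Itgae and Arl5a Treg-like ones, and S1pr1 (3.98-fold), Dapl1, Klrg1 and Itgb8 were among the genes named by size. Chemokine genes (1.13) and inflammatory genes (1.41, 16 and 0), most of them made chiefly by myeloid cells, were also higher in T-like cells, and under 3 inflammatory genes passed the criterion for free RNA, which leaked from other cells.

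In CD8-like cells, compared within the subset, the combination had a higher cytotoxicity list than the control (0.54, 13 and 3), while against anti-PD-1 its median of 0.07 was not apart from random lists. Gzmf was 5.62-fold [5.32 to 5.94], Gzme 3.07-fold, Gzmd 2.81-fold, Gzmb 2.04-fold and Prf1 1.47-fold the control. Interferon-gamma genes were higher with 17 of 17 members (0.84), and naive or stem-like genes were at 0.29 (9 and 3). Inhibitory receptors were lower in the median (-0.48) with 5 members higher and 6 lower. Tox was 0.264-fold, Nr4a2 0.433-fold and Pdcd1 0.718-fold. Lists of myeloid cells were higher there as well, chemokine genes at 1.30, inflammatory genes at 1.23 and suppressive macrophage genes at 1.01. The CD8-like cells of the control lay most often in subcluster 0 (44.0%) and those of the treated libraries in subcluster 8 (47.6%, 56.8% and 51.1%).

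In myeloid cells of the combination library 17 of 20 lists stood apart from the control in neutrophil-like and 15 of 20 in phagocyte-like cells, against 12 and 14 after anti-PD-1 and 13 in both after CCL21-DC. Neutrophil-like cells had all 18 interferon-gamma genes higher (0.86), with Iigp1 at 10.7-fold, and higher inflammatory genes (0.60, 15 and 2), with Nos2 at 5.95-fold and the chemokines Ccl4 and Ccl3 at 3.72-fold and 3.03-fold. Their oxidative phosphorylation genes were lower with 15 of 15 members after each treatment, by medians of -0.69 after anti-PD-1, -0.70 after CCL21-DC and -1.01 after the combination. In these cells the median of all genes was itself shifted, by -0.38, -0.28 and -0.71. Relative to most genes, by TMM scaling, the interferon-gamma medians were 1.30, 0.80 and 1.48, the inflammatory medians 1.03, 1.03 and 1.22, and the oxidative phosphorylation medians -0.36, -0.47 and -0.39. Cytotoxicity genes, which T and NK cells chiefly make, were higher in neutrophil-like cells too (0.71, 0.88 and 0.88), and under 3 of them passed the criterion for free RNA. Neutrophil-like cells also lay mostly in different clusters, the control's most often in cluster 1 (38.2%) and those of the treated libraries in cluster 5 (26.6%, 21.8% and 48.8%).

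Phagocyte-like cells of the combination library had higher interferon-gamma (1.46, 16 and 2), inflammatory (1.00, 17 and 1), lysosome and lipid (0.73, 14 and 2) and dendritic cell maturation genes (0.35, 11 and 4). Cxcl10 was 6.82-fold [5.88 to 7.95], Socs1 4.86-fold, Tnf 3.73-fold and Cxcl9 0.570-fold the control. MHC class II genes were lower (-0.41, 1 and 8), with H2-Aa at 0.625-fold and Cd74 at 0.796-fold. The makeup of the class differed too, with cDC1-like cells at 0.435-fold [0.226 to 0.794] and macrophage-like cells at 0.577-fold the control share. Monocyte-like cells were at 1.77-fold. In the CD3 pair the macrophage-like ratio was 1.00 [0.743 to 1.35] and the monocyte-like ratio 0.967 [0.547 to 1.70], so this difference was seen in the CD45 pair alone. Proliferation genes were lower with 18 of 18 members (-3.27), with Mki67 at 0.0906-fold [0.0487 to 0.147] and Top2a at 0.0594-fold. The size of that difference depended on cells that held the transcripts of 2 lineages: with those kept, the medians were -0.55, -0.69 and -1.32 after anti-PD-1, CCL21-DC and the combination, and with barcodes found in several libraries kept as well, -0.73, -0.31 and -0.41. The control's phagocyte-like cells lay most often in cluster 0 (27.2%) and those of the treated libraries in cluster 12 (20.8%, 15.6% and 22.4%).

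**Figure D3:**
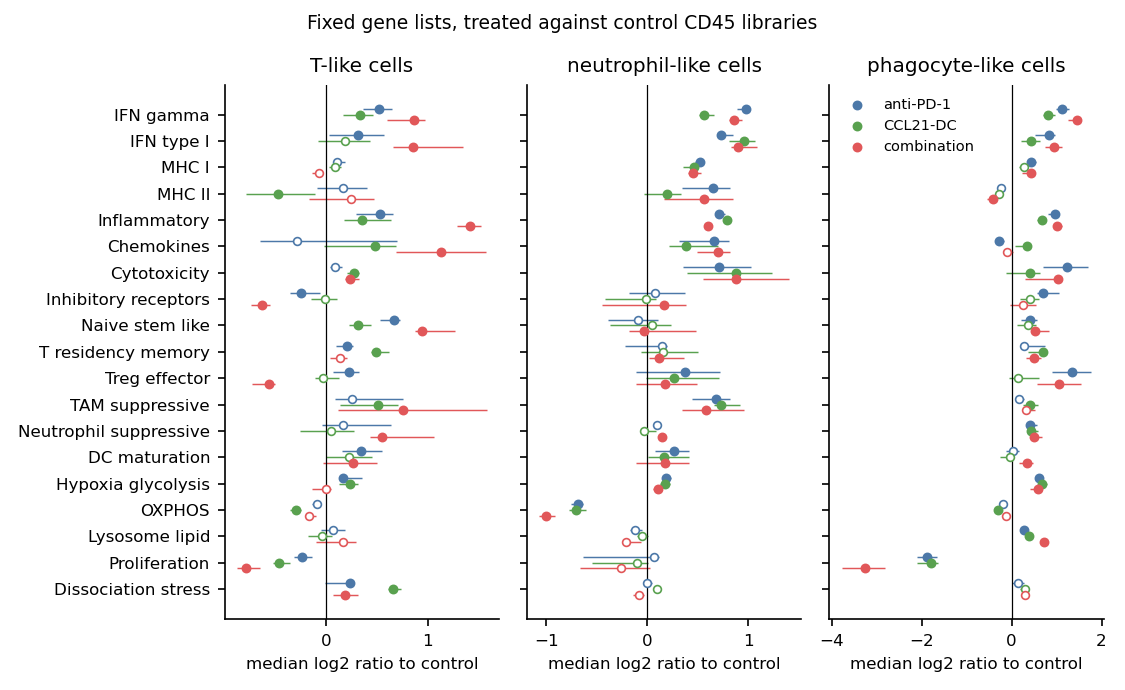
Each point is the median log2 ratio of a gene list to the control after anti-PD-1, CCL21-DC or the combination, in T-like, neutrophil-like and phagocyte-like cells of the CD45 libraries, with lines for 95% counting intervals. Filled points lie outside the central 95% of random lists and open points inside, and interferon-gamma genes lie above 0 in every panel, from 0.34 to 1.46.

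Among the genes named by size in the combination library, Gzmf was 4.21-fold [3.99 to 4.44] the control in T-like cells and Ccl1 5.83-fold lower, beside Slc16a11 and Nrgn. UMIs of 1 cell are not independent, so the intervals of genes held by few cells are too narrow; Ccl1 was detected in 21 combination and 15 control cells. In neutrophil-like cells Serpinb2 was 17.7-fold, Csf3 13.6-fold [10.6 to 18.1], Gbp4 10.8-fold [9.96 to 11.8], Il1f6 7.73-fold and F3 6.23-fold the control. The lowest there were Ltc4s (10.2-fold lower), Siglecf (8.73-fold lower), H1f0, Dclre1b and Ilf2. In phagocyte-like cells Nos2 was 10.2-fold [8.24 to 12.7], the acute phase gene Saa3 9.69-fold, Pdpn 8.15-fold, Serpinb2 11.2-fold and Atp6v0d2 11.5-fold, the last in 16 combination and 5 control cells. The unnamed cluster with Atp6v0d2 among its leading genes, with 65 control and 15 combination cells, is not part of this ratio. Retnla had no UMI in the combination and was at least 17.8-fold lower, and the cell cycle genes Cdca3, Nusap1 and Ccna2, without UMIs as well, were at least 15.7-fold, 13.5-fold and 13.1-fold lower. Ube2c, with 3 UMIs, had a ratio of 0.0278 [0.00489 to 0.0704].

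A few of these genes, placed on the mouse genome build GRCm38, are given with their levels in UMIs per 1000000 UMIs of the class (CPM). Irgm2 (ENSMUSG00000069874, chromosome 11, 58199618 to 58222782) stood at 27.7 CPM [23.7 to 32.1] in T-like cells of the combination and 5.59 CPM [3.41 to 8.63] in the control. Ccl1 (ENSMUSG00000020702, chromosome 11, 82176657 to 82305690) stood at 39.2 CPM [34.5 to 44.4] against 228.7 CPM [213.3 to 245.0]. In neutrophil-like cells Csf3 (ENSMUSG00000038067, chromosome 11, 98701263 to 98703629) was at 89.7 CPM [83.1 to 96.6] against 6.53 CPM [5.01 to 8.35], and Siglecf (ENSMUSG00000039013, chromosome 7, 43351341 to 43359531) at 7.52 CPM [5.71 to 9.72] against 66.2 CPM [61.2 to 71.5]. In phagocyte-like cells Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254) was at 299.0 CPM [272.7 to 327.2] against 29.3 CPM [24.0 to 35.5].

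Comparing the combination with each single treatment asks what differed when both were given. In T-like cells the Treg effector list was lower than after anti-PD-1 (-0.84, 1 and 16) and after CCL21-DC (-0.77, 2 and 15), with Il2ra, the interleukin 2 receptor alpha chain, at 0.490-fold and Foxp3 at 0.432-fold the anti-PD-1 level. Type I interferon genes were higher against both (0.86, 13 and 2; 0.87, 14 and 1), and proliferation genes lower with 18 of 18 members against both (-0.52 and -0.33). Inhibitory receptors were lower too (-0.33, 0 and 11; -0.36, 2 and 9). Against CCL21-DC, residency genes were lower with 11 of 11 members (-0.45), among them Cxcr6 at 0.75-fold, and naive or stem-like genes were higher (0.85, 9 and 4). Several of these medians did not hold within subsets: Treg effector genes in Treg-like cells were at 0.03 against anti-PD-1 (not apart) and -0.20 against CCL21-DC, inhibitory receptors in Treg-like cells at 0.71 against anti-PD-1 and apart in no subset against CCL21-DC. Also against CCL21-DC, naive or stem-like genes were lower within CD8-like (-0.43) and conventional CD4-like cells (-0.34), and proliferation genes were not apart within CD8-like (-0.14) and Treg-like cells (-0.04). In CD8-like cells cytotoxicity genes were higher than after CCL21-DC (0.24, 12 and 4). The genes named by size in T-like cells included Gzmf (5.16-fold) and Gzmd (2.32-fold) against anti-PD-1, with Itgae 3.25-fold lower and Ttn, Rflnb and Arl5a at either end. Il13 was 7.68-fold against anti-PD-1, and lower instead under 3 alternatives. Against CCL21-DC, Ifngr2 was 5.02-fold, Iigp1 4.57-fold, Il6ra 4.54-fold and Trib2 3.84-fold. The cytokine Csf2 was 4.43-fold lower, the heat shock gene Hspa1b 2.95-fold lower and Ifng 2.40-fold lower, beside Hspa1a and, from 1 cell for the most part, Ccl1.

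Phagocyte-like cells of the combination library had more dendritic cell maturation transcripts than those of either single treatment (0.49, 13 and 3; 0.47, 15 and 0), with the costimulatory receptor gene Cd40 at 1.88-fold the anti-PD-1 and 2.15-fold the CCL21-DC level. Proliferation genes were lower with 17 of 17 members in both comparisons (-0.94 and -0.86). Under the first planned filters the medians against the control were -0.73, -0.31 and -0.41 after anti-PD-1, CCL21-DC and the combination. The proliferation list of the combination was not compared directly with either single treatment under the alternatives, so whether it was lower there is not known. With only cells of 2 lineages kept, the medians were -0.55, -0.69 and -1.32. The suppressive macrophage list was lower against CCL21-DC (-0.40, 6 and 11), with Mrc1 at 0.405-fold and Mgl2 at 0.419-fold, and was not apart from random lists against anti-PD-1 (0.13). By size, Saa3 was 9.49-fold [6.37 to 15.2] the anti-PD-1 and 10.9-fold the CCL21-DC level. Serpinb2 (4.71-fold), Tgm1, Slpi and Fabp5 were the next highest against anti-PD-1, where Sept3 was 7.01-fold lower, and the other lowest, Ifng, Ccl8, Hspb1 and Ube2c, took most of their UMIs from 1 cell; Ifng turned under 2 alternatives and Ube2c under the first planned filters. Cxcl10 (2.95-fold), Ccl22 (3.07-fold), Il4i1 (3.27-fold) and Ccr7 (2.52-fold) were highest against CCL21-DC, where the receptor kinase Axl was 4.30-fold, Mmp13 3.87-fold, Top2a 5.52-fold and Rrm1 5.08-fold lower, and Retnla, without UMIs in the combination and mostly from 1 CCL21-DC cell, at least 16.9-fold lower. C1qb, Axl, Mmp13, Mgl2 and Atp6v0d2 are leading genes of macrophage-like, Nos2 and Cxcl10 of monocyte-like, Sept3 of cDC1-like and Ccl22, Il4i1 and Ccr7 of mregDC-like subclusters. In neutrophil-like cells 6 of 20 lists stood apart against anti-PD-1 and 9 of 20 against CCL21-DC, and the interferon-gamma list was at -0.01 (not apart) and 0.30 (16 and 2). The named genes there included Gbp4 (2.73-fold), Stfa3 (3.63-fold), Prok2 and Retnlg above and Klhl6 (2.87-fold lower), C5ar2, Sla, Havcr2 and B3gnt5 below the anti-PD-1 level. Against CCL21-DC they were the granule genes Ngp (3.63-fold) and Lcn2 (2.11-fold) with Csf3 (2.5-fold), Timp2 and Il1f6 above, and Mustn1, Ptgs1 (3.92-fold lower), Cysltr1, Klhl6 and Arf2 below.

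The 4 CD45 libraries form a 2 by 2 design, so the combination was set against the sum of the log2 ratios of both single treatments. The departures of lists were not compared with random lists. In 6646, 5430 and 5003 genes with at least 200 UMIs in T-like, neutrophil-like and phagocyte-like cells, the slopes of the combination against that sum were 0.440, 0.667 and 0.557, and the median departures were -0.11, -0.05 and -0.09. Interferon-gamma genes lay below the sum in neutrophil-like (-0.68, 2 members above and 16 below) and phagocyte-like cells (-0.60, 1 and 17). In T-like cells type I interferon genes lay above it (0.67, 12 and 3) and Treg effector genes below it (-0.83, 1 and 16). Dendritic cell maturation genes lay above it in phagocyte-like cells (0.67, 12 and 3). Gzmf in T-like cells exceeded the sum by 1.88, and Ifng fell short of it with a departure of -1.84. T-like cells were taken as 1 class here, though their Treg-like share was 23.5%, 21.9%, 13.9% and 6.99% in the 4 libraries. Their naive-like share was 10.0%, 13.5%, 3.13% and 36.9%. The shares within phagocyte-like cells differed too, so these departures cannot be told apart from differences in makeup. The control counts enter the sum 2 times, so error in the control alone pushes departures against the sum; their correlation with it was -0.761, -0.683 and -0.773.

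The profiles of the 3 treatments against the control were alike across genes, which are not independent replicates. In T-like cells the correlations of the log2 ratios were 0.651, 0.632 and 0.613, in neutrophil-like cells 0.776, 0.835 and 0.775, and in phagocyte-like cells 0.772, 0.783 and 0.760. Because each pair shares the control, simulated libraries without any effect gave correlations of 0.479, 0.555 and 0.553 in T-like, 0.340, 0.394 and 0.382 in neutrophil-like, and 0.387, 0.342 and 0.346 in phagocyte-like cells. The covariances observed were 0.0819, 0.0886 and 0.0988 against simulated 0.0251, 0.0266 and 0.0266 in T-like cells, 0.206, 0.333 and 0.278 against 0.0174, 0.0193 and 0.0191 in neutrophil-like cells, and 0.211, 0.274 and 0.271 against 0.0225, 0.0214 and 0.0216 in phagocyte-like cells. The simulated libraries held counting error alone. Any other way in which the control library stood apart also adds to the observed values, so the excess does not measure likeness of the treatments.

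The libraries labelled CD3 repeat the contrast of combination and control, and ask which T cell subsets differed there. T-like cells formed 14.8% of kept cells in the control (454 cells) and 58.6% in the combination (1381 cells), a ratio of 3.95 [3.55 to 4.40], although cells selected by CD3 should hold little else. Naive-like cells formed 9.69% of T-like cells in the control and 71.1% in the combination, a ratio of 7.34 [5.42 to 10.2]. Treg-like cells formed 61.5% and 11.7%, a ratio of 0.190 [0.155 to 0.231], conventional CD4-like cells 15.2% and 10.4%, and CD8-like cells 13.7% and 6.81%. Without naive-like cells, CD8-like cells formed 15.1% and 23.6%, conventional CD4-like cells 16.8% and 36.1%, and Treg-like cells 68.0% and 40.3%, which are ratios of 1.56 [1.12 to 2.18], 2.14 and 0.593 [0.485 to 0.723]. T-like cells other than naive-like ones formed 13.4% and 16.9% of kept cells. B-like cells were 0 of the control's 3059 kept cells, taken at a limit of 3 counts (0.0981%), and 0.297% of the combination's. The naive-like ratio was 12.3 to 14.3 under 6 of the alternatives, the CD8-like ratio of 0.498 turned to 1.09 under the gate on subset transcripts, and the conventional CD4-like ratio of 0.686 to 1.02 at Leiden resolution 2. Cells holding transcripts of 2 lineages, left out of all classes, were 16.5% and 26.3% of the cells that passed the other filters, and median UMIs per T-like cell were 2910 and 3538.

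Within T subsets of the CD3 libraries, CD8-like cells of the combination had more cytotoxicity transcripts (0.69, 13 and 3), with Gzmd at 3.22-fold, Gzme at 3.15-fold, Gzmf at 2.98-fold, Gzmb at 2.14-fold and Ifng at 2.37-fold the control. Interferon-gamma (0.76, 14 and 0), naive or stem-like (0.88, 9 and 3), residency (0.64, 9 and 1) and proliferation genes (0.30, 16 and 2) were higher, as was the T helper list (1.25, or 0.90 with members at 0 placed at their bound, and 0.51 when cells had to hold at least 500 genes). Lists of other cells were higher in CD8-like cells as well: suppressive neutrophil (1.04, 7 and 1), Treg effector (0.79, 12 and 2), suppressive macrophage (0.61, 9 and 1, but 0.42 at the bound, inside the random range) and inflammatory genes (0.52, 11 and 3). Conventional CD4-like cells had higher interferon-gamma (1.20, 13 and 1), cytotoxicity (0.60, 12 and 2), residency (0.66) and hypoxia and glycolysis genes (0.54), with Gbp2 at 2.40-fold. In these cells the median of all genes was shifted by 0.11. Their proliferation list was at -1.47 (2 and 9), and at 0.16 when each gene needed at least 50 UMIs. Treg-like cells had higher Treg effector genes (0.65, 15 and 2), with Il2ra at 2.06-fold [1.82 to 2.33], Tnfrsf9 at 1.78-fold and Foxp3 at 1.31-fold, higher interferon-gamma (0.48, 13 and 3) and naive or stem-like genes (0.64, 9 and 1), and lower proliferation genes (-0.42, 3 and 15). The median of all genes in Treg-like cells was shifted by 0.14. Conventional CD4-like cells lay most often in subcluster 1 in the control (65.2%) and in subcluster 7 in the combination (68.1%).

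The genes named by size in CD8-like cells were Gzmc (5.05-fold [4.16 to 6.24]), Gzmg (4.42-fold), Tnfsf8, Ms4a4c and, from 1 cell for the most part, Olfr1369-ps1, with Lars2 (2.24-fold lower), Bin1, Mt1, Sgta and Fbl lowest. Control UMIs of Gzmg, Tnfsf8, Ms4a4c and Olfr1369-ps1 came from 1 cell each, and Gzmg was detected in 9 combination cells. Gzmc (ENSMUSG00000079186, chromosome 14, 56231441 to 56234656) stood at 1279 CPM [1212 to 1350] against 252.3 CPM [206.6 to 305.1]. In conventional CD4-like cells they were Kdm6b (4.94-fold [3.06 to 9.05]), Ly6c2 (10.6-fold [3.51 to 111]), Serpinb1a, Mxd1 and Gabpb1, with the secreted phosphoprotein gene Spp1 7.68-fold lower beside Cst3, Igfbp7, Rfc2 and Lars2. In Treg-like cells Nr4a3, induced by T cell receptor signals, was 8.74-fold [4.38 to 22.3], and Penk 3.81-fold, Socs1 3.60-fold, Gramd3 3.27-fold and Mxd1 2.58-fold the control. Tpx2 was 3.84-fold lower and Mki67 2.14-fold lower, beside Knstrn, Hadh and Lars2. Across all T-like cells the CD3 combination had lower Treg effector (-1.15, 1 and 16), inhibitory receptor (-0.58, 1 and 10) and proliferation genes (-1.01, 0 and 18) and higher naive or stem-like genes (1.61, or 1.46 at the bound). The subset shares differed as well. Within subsets, inhibitory receptors were at 0.008 in CD8-like, 0.006 in conventional CD4-like and 0.44 in Treg-like cells, none apart from random lists. Treg effector genes were higher within Treg-like (0.65) and CD8-like cells (0.79), and proliferation genes higher within CD8-like cells (0.30).

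Whether both pairs of libraries gave the same contrast was asked by comparing log2 ratios of combination to control between the CD45 and the CD3 libraries, which share no library. In T-like cells the correlation across 7835 genes was 0.619 (Spearman 0.555), and 70.5% of genes had the same sign. In neutrophil-like cells it was 0.830 (Spearman 0.813) over 3988 genes, with 87.5% on the same side, in phagocyte-like cells 0.680 over 4746 genes, and in tumour-like cells 0.631 over 10320 genes. Within T subsets it was lower, 0.362 in CD8-like, 0.422 in conventional CD4-like and 0.350 in Treg-like cells. Libraries redrawn without any effect gave correlations between -0.0268 and 0.0283 in T-like cells and between -0.0339 and 0.0310 in neutrophil-like cells. Genes are not independent replicates, and the subsets hold fewer cells and UMIs than all T-like cells. The subset shares of T-like cells also differed in the same direction in both pairs. Naive-like cells formed 10.0% and 36.9% in the CD45 and 9.69% and 71.1% in the CD3 control and combination, and Treg-like cells 23.5% and 6.99%, and 61.5% and 11.7%. Such a difference in makeup adds to the correlation of all T-like cells, so 0.619 does not measure expression within subsets alone.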

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

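Of the tests below, those on copied barcodes, on blood or lymph node cells, on the injected cells, on the control library alone and on random pairs, and the values of further lists in neutrophil-like cells, were chosen only after the result was seen. The proliferation list of CD8-like cells lay on opposite sides in the CD45 and CD3 libraries, which is what drew attention to it: the median log2 ratio of combination to control was -0.19 [-0.32 to -0.14] in the CD45 libraries and 0.30 [0.20 to 0.48] in the CD3 libraries, and the difference was not tested. Signal outside the main measurement was found in the libraries labelled CD3, whose selection is not stated: neutrophil-like cells formed 31.2% [29.6 to 32.9] of the control and 21.6% [19.9 to 23.3] of the combination library, and tumour-like cells 46.3% [44.5 to 48.1] and 10.4% [9.24 to 11.8]. A further 365 barcodes occurred in several libraries without any library that held at least 5 times the UMIs of each other one.

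Naive-like T cells were more frequent in both combination libraries. Copies of the same barcodes in both libraries were excluded as the whole cause, since 0% (0 of 538) of these cells in the CD45 library, with shared barcodes kept, had a barcode that the CD3 combination library also held. The injected cells alone as a draw for naive cells stay open: the naive-like share of kept cells after CCL21-DC was 0.529-fold [0.293 to 0.913] the control, but in 1 library with 18 such cells. Blood or lymph node cells taken along with the tumour may be the source: B-like cells, which both tissues hold, had a share 7.41-fold [4.43 to 13.2] that of the control. Hemoglobin genes, which mark red blood cells, did not rise with them. They stood at 0.387 CPM [0.221 to 0.628] in the CD45 combination and 0.370 CPM [0.223 to 0.578] in its control. In the CD3 libraries they stood at 0.732 CPM in the combination and 150.9 CPM in the control. These values give no sign of more blood in the combination. They do not bear on lymph node cells, or on white blood cells if red cells had been removed, so this source stays open. An effect of the combination on the entry of naive cells was not tested and stays open, and treatment and library cannot be told apart.

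Neutrophil-like cells of all treated libraries differed from the control, in interferon-gamma, inflammatory and oxidative phosphorylation genes among others. The CD3 libraries argue against a CD45 control library that stands apart alone, since that other pair gave log2 ratios that correlated at 0.830 across genes. Whether both controls came from the same mice is not stated. Median UMIs of neutrophil-like cells were also higher in the combination of both pairs (3416.5 against 2364.5 and 2380 against 1294). A difference common to both pairs other than the treatment thus stays open. Part of the likeness among the 3 treatments may still come from the control they share. Depth is excluded as the cause for interferon-gamma genes, because in cells with 1756.5 to 4678 UMIs their median after anti-PD-1, the treatment with the smallest share kept, was 0.93 against 0.98 in all cells. For free RNA of other cells, the smallest interferon-gamma median was 0.56 over members that pass the criterion, so members under it do not carry the rise. The criterion compares levels between classes and does not measure free RNA, and the same list was higher in tumour-like cells, so free RNA is not excluded. It stays open for Treg effector genes as well, where these medians were -0.17, -0.06 and -0.51, and for cytotoxicity genes, of which under 3 pass. For interferon-gamma genes an effect of the treatments is thus consistent with these values, as a hypothesis from the same data, but the design cannot separate it from the libraries.

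Cells that passed the T and phagocyte panels alone numbered 46, 72, 82 and 87 in the CD45 and 73 and 186 in the CD3 libraries, and a further 53, 95, 68, 159, 76 and 255 also passed the neutrophil panel. Random pairs in 1 droplet stay open: the former were 6.81 to 14.6 times as frequent against T with neutrophil cells as phagocytes against neutrophils, but 1.92 to 3.93 times with cells of all 3 panels counted as T with neutrophil. Free RNA at an even level within each library is excluded as the whole cause, since it would give 0.0872 such cells in all libraries where 546 were seen. That level came from T cells that fail the phagocyte panel, so free RNA that differs between droplets stays open. The median of the 546 cells, 14746 UMIs, was above that of T (3679.5) and of phagocyte cells (7190), as 2 cells in a droplet would give. Bound pairs of cells and uptake of T cells by phagocytes were not tested and stay open.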

How the results depend on the processing

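The alternatives that kept shared barcodes, cells with transcripts of 2 lineages, or both (the filters as first planned), were chosen after seeing the data; the others were planned. Counting a result once for each alternative, the main list medians kept their values within the counting interval in 84 of 105 cases, moved in 20 and reversed in 1; the main share ratios were kept in 77 of 106 cases, moved in 27 and reversed in 2. Other list medians were kept in 944 of 1203 cases (238 moved, 21 reversed), named genes in 1176 of 1420 (231 moved, 13 reversed) and other share ratios in 223 of 246 (16 moved, 7 reversed). Values of the comparison between the CD45 and CD3 libraries and of additivity moved in 21 of 32 cases and reversed in 0; redrawing counts can only weaken a correlation, so any higher value counted as moved. Unless a cause is given, the cause was not tested. Depth limits the CD3 subsets, with 62 CD8-like and 69 conventional CD4-like cells in the control, naive-like cells of the CD45 control, with 57 cells, and genes with few UMIs in any class. No paired analysis was possible because the labels pair no mice or libraries between the groups.

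For shares, the naive-like ratio of the CD3 libraries (7.34) became 12.3 with called doublets kept, 14.0 with up to 20% mitochondrial UMIs, 10.7 with at least 500 genes per cell, 12.4 and 14.0 at Leiden resolutions 0.5 and 2, 14.3 with shared barcodes kept and 13.8 with the filters as first planned. In the CD45 libraries the same ratio (3.69) became 5.74 with 20% mitochondrial UMIs, 5.23 at Leiden resolution 2, 5.01 with shared barcodes kept and 5.26 with the first filters. The CD8-like ratio of the CD45 combination (0.707) became 0.583 both at 500 genes and at Leiden resolution 2, and 0.557 with the first filters. At Leiden resolution 2 the conventional CD4-like ratio of the CD3 libraries turned from 0.686 to 1.02. Under the gate on subset transcripts the CD3 ratio turned from 0.498 to 1.09 for CD8-like cells, the Treg-like ratio was 0.231 instead of 0.190, and that of the CD45 combination 0.448 instead of 0.297. At 500 genes the CCL21-DC ratio turned from 1.69 to 0.964 for T-like cells, most of which were then called mixed, and from 0.592 to 1.01 for Treg-like cells. The T-like ratio of the combination (2.97) was 2.67 by the gate on T cell transcripts and 2.64 with the first filters, where that of anti-PD-1 (1.48) was 1.26. Among cells other than neutrophil-like ones, a smaller denominator by construction, the T-like ratios were 1.14, 1.21 and 1.88 after anti-PD-1, CCL21-DC and the combination; there the tumour-like ratios turned to 0.906 after anti-PD-1 and 0.887 after CCL21-DC, and the phagocyte-like ratio after CCL21-DC to 0.888. The tumour-like ratio turned to 0.911 after anti-PD-1 with 20% mitochondrial UMIs and to 1.30 after the combination with the first filters. The neutrophil-like ratios were 0.746 after anti-PD-1 and 0.598 after the combination with shared barcodes kept, and 0.703, 0.709 and 0.561 after the 3 treatments with the first filters.

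For list medians, TMM scaling, which takes out the shift of all genes in neutrophil-like cells, gave 1.30 for interferon-gamma after anti-PD-1, 1.20 for type I interferon after CCL21-DC and -0.39 for oxidative phosphorylation after the combination. With cells of 2 lineages kept these were 0.82, 0.63 and -0.41. The proliferation medians of phagocyte-like cells after anti-PD-1, CCL21-DC and the combination (-1.88, -1.80 and -3.27) became -0.55, -0.69 and -1.32 with cells of 2 lineages kept and -0.73, -0.31 and -0.41 with the first filters, and the first and last -2.29 and -2.82 with equal weight per cell. In T-like cells the naive or stem-like median after anti-PD-1 (0.67) was 0.74 with shared barcodes kept and 0.45 with equal weight per cell, and the inflammatory median after the combination (1.41) was 1.14 at 500 genes. The T helper median after CCL21-DC (0.73) was 0.46 at 500 genes and 0.46 with cells of 2 lineages kept, and that of CD8-like cells in the CD3 libraries (1.25) was 0.51 at 500 genes. The proliferation median of conventional CD4-like cells in the CD3 libraries turned from -1.47 to 0.16 with at least 50 UMIs per gene, which leaves fewer genes.

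Further list medians turned. With equal weight per cell these were type I interferon after anti-PD-1 (-0.059), and cytotoxicity (-0.034) and naive or stem-like genes (-0.0042) after CCL21-DC in T-like cells, and in phagocyte-like cells naive or stem-like genes after anti-PD-1 (-0.029) and chemokines after CCL21-DC (-0.076). At 500 genes chemokines after CCL21-DC in phagocyte-like cells (-0.048) turned, as did inflammatory genes after CCL21-DC (-0.070) and the T helper list after the combination (-0.42) in T-like cells. With cells of 2 lineages kept, chemokines (-0.047) and suppressive neutrophil genes (-0.075) after CCL21-DC and cytotoxicity (-1.59) after the combination turned in phagocyte-like cells, and MHC class II (-0.089) and suppressive neutrophil genes (-0.037) after the combination in neutrophil-like cells. With the first filters, MHC class II (-0.051), suppressive neutrophil (-0.068) and suppressive macrophage genes (-0.24) turned after the combination in neutrophil-like cells, suppressive neutrophil genes (-0.13) after CCL21-DC in phagocyte-like cells, and MHC class II (0.017) after CCL21-DC in T-like cells. Over members that pass the free RNA criterion, dissociation stress after the combination (-0.18) and suppressive macrophage genes after CCL21-DC (-0.027) turned in T-like cells, and Treg effector genes after anti-PD-1 (-0.26) in phagocyte-like cells.

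Among named genes, at 500 genes the log2 ratio after anti-PD-1 turned to 1.14 for Gzmg and 0.34 for Spp1 in T-like cells and to -0.99 for Ifng in phagocyte-like cells, and that of the combination to anti-PD-1 to 2.16 for Ifng in phagocyte-like and -3.45 for Il13 in T-like cells. Il13 in that comparison was also -0.61 with called doublets kept and -1.45 with cells of 2 lineages kept. With the latter, Ifng in phagocyte-like cells after anti-PD-1 was -1.49 and Atp6v0d2 after CCL21-DC -0.090. With shared barcodes kept, Ifng of the combination to anti-PD-1 in phagocyte-like cells was 2.22. With the first filters, Ccna2 in phagocyte-like cells after anti-PD-1 was 0.15, Ube2c of the combination to anti-PD-1 0.52, and Mmp13 in neutrophil-like cells after CCL21-DC -0.56.

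Between the CD45 and CD3 libraries, the correlation in T-like cells (0.619) was 0.624 with shared barcodes kept, 0.621 with cells of 2 lineages kept, 0.636 with the first filters and 0.722 with at least 200 UMIs in each pair, and the percent of genes with the same sign (70.5) was 70.6, 70.6, 70.9 and 73.6. In neutrophil-like cells the correlation (0.830) was 0.832 with the first filters and 0.909 with 200 UMIs, and the percent with the same sign (87.5) was 81.7 with TMM, 82.1 with cells of 2 lineages kept and 87.9 with the first filters. The median departure from additivity, -0.11, -0.05 and -0.09 in T-like, neutrophil-like and phagocyte-like cells, was -0.011, -0.00095 and -0.056 with TMM and -0.086, -0.13 and -0.057 with cells of 2 lineages kept. In phagocyte-like cells it was -0.066 with shared barcodes kept and -0.097 with the first filters.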

Other observations

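No tests were run for the values in this part. Tumour-like cells carried the strongest interferon-gamma list of all classes compared. All 18 members were higher than in the control after anti-PD-1 (median log2 ratio 1.89), CCL21-DC (0.98) and the combination (2.16), and in the CD3 pair (2.46). Iigp1 was 5.46-fold, 3.06-fold, 7.47-fold [7.02 to 7.96] and 9.05-fold the control in these comparisons, and Gbp2 4.30-fold, 2.12-fold, 5.60-fold and 7.10-fold. Antigen presentation went with it: MHC class I genes were higher with 15 of 15 members (1.25, 0.73, 1.22 and 1.43), with B2m at 2.37-fold, 1.79-fold and 2.41-fold in the CD45 libraries, and MHC class II genes were higher too (1.98, 0.60, 2.07 and 1.93), with Cd74 at 5.24-fold, 1.79-fold, 5.38-fold and 6.25-fold. Lists of other cell types were higher in tumour-like cells as well, cytotoxicity by 1.14, 1.08, 1.07 and 0.83 and T cell residency by 0.86, 1.45, 0.90 and 2.02. Cd274, the gene of PD-L1, was 4.61-fold after the combination. Proliferation genes were slightly lower in the CD45 libraries (-0.31, -0.32 and -0.21) and higher in the CD3 pair (0.41).

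NK-like cells had higher cytotoxicity lists (0.27, 0.19 and 0.57 after anti-PD-1, CCL21-DC and the combination). After the combination Gzmf was 22.6-fold [20.2 to 25.5], Gzmd 21.4-fold [18.3 to 25.4], Gzme 11.3-fold [9.10 to 14.3], Gzmc 3.99-fold and Prf1 2.06-fold the control. The suppressive neutrophil list stood at 0.10 and -0.04 in neutrophil-like cells after anti-PD-1 and CCL21-DC, not apart from random lists, and at 0.15 after the combination, which turned under 2 alternatives but was 0.76 by TMM scaling; in the CD3 pair it was 0.53. Pdcd1, the target of the antibody, stood at 33.4, 35.1, 39.0 and 47.9 CPM over all cells of the CD45 libraries and at 11.8 and 31.5 CPM in the CD3 libraries, and Ccr7, the receptor of CCL21, at 28.4, 38.6, 26.0, 56.7, 10.6 and 99.7 CPM. Ccl21a, Ccl21b, Ccl21c and Ccl19, the rest of the CCL21 axis list, had 0 UMIs in every library, with limits of 0.0541 to 0.0838 CPM; how reads of near-identical gene copies were counted is not stated, so the level of the injected chemokine was not judged. Hemoglobin genes stood at 150.9 CPM in the CD3 control and at 0.363 to 0.732 CPM in the other libraries.

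Of the barcodes found in several libraries, 1321 had a library with at least 5 times the UMIs of any other, and their 3674 copies elsewhere held a median of 1.90% of its UMIs. The 365 others, in 1443 entries, carried genes of myelinating cells, with Mal at 199.9 CPM against 0.301 in kept cells, Ptgds at 168.3 against 0.127, Mag at 133.7 against 1.06 and Mobp at 94.1 against 0.0335. Their leading genes also held Fcrls at 82.3 against 0.491 and the macrophage marker C1qc at 370.0 against 38.7. The main comparisons leave these barcodes out.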
